A study of Mus musculus with 15 samples.

How the data were processed

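RNA immunoprecipitation libraries of mouse were analysed from gene counts deposited by the authors, 1 table per library. Per the labels' protocols, tail fibroblast lines came from WT, Het and Hom littermates of the same sex. For the Dnmt1 RIP, cells were fixed in 1% formaldehyde and precipitated with a rabbit antibody against Dnmt1. For the m5C RIP, 1 ug of messenger RNA isolated on oligo-dT beads was precipitated with an antibody against 5-methylcytosine. The labels' protocols name both ribosomal RNA depletion and polyA enrichment before an NEBNext Ultra II library, and which was used for which library is not given in the sources used here. Reads were trimmed with Trim Galore 0.4.1, aligned with HISAT2 to mm10 and counted with featureCounts, per the submitters' processing notes; the versions of the latter tools, the annotation and the strand setting are not given in the sources used here. Groups were taken from the titles.

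Each deposited table holds raw counts for 31017 gene symbols, of which 30464 matched GENCODE M21 and gave coordinates and lengths on mm10. The tables of 6 libraries (fibroblast m5C Het and Hom, cortex) also hold 5 entries for reads in no gene, in the layout of another counting program than the one in the notes. These entries were kept out of library sizes and tests. Among these libraries, 63.2 to 89.5% of all entries were not aligned, 4.36 to 18.4% fell in no gene and 3.79 to 10.1% in genes; the other 9 tables hold genes alone. Total gene counts ranged from 217173 to 4913482. A count of 0 was taken to allow up to 3 counts, and intervals of shares are 95% exact binomial intervals.

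Tests used edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total 15), TMM factors, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05 over the genes tested. The fits, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The Dnmt1 RIP fit held 6 libraries and genotype (common biological coefficient of variation 0.424, 3 residual degrees of freedom). The fibroblast m5C fit held 4 libraries (0.247, 1 residual degree of freedom, from the WT pair alone, the lone mutant library being assumed to vary like WT). Both tissues were fitted with tissue as a covariate (0.205), m5C RIP over input with tissue and genotype (0.434), the assay interactions and the WT comparison of the antibodies in 10 fibroblast libraries (0.406), and the Dnmt1 RIP over input in 7 libraries (0.446). Standard errors are the log2 fold change divided by the square root of F. Gene lists (36, members past the filter) were tested with camera in limma 3.58.1, two-sided, with the preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Cortex libraries were compared as log2 ratios with a prior count of 2, and list medians were ranked among 10000 random lists. These lists were matched on mean expression and drawn without regard to correlation between genes. A fold against a group with 0 counts is given as a bound against 3 counts in each library.

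Genes were named by rule: the 12 largest changes per direction past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out genes with placeholder names; where none passed, the 5 smallest p per direction; in each list described, up to 4 members with the smallest p; in cortex the 10 largest ratios per direction with at least 50 counts; and always Dnmt1, Xist and Y-linked genes.

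The fits were tested on simulated data with 200 genes changed. Of the 16-fold changes, 87.9% were recovered for Hom against Het in the Dnmt1 RIP (13589 genes). For Hom against WT, 89.4% were recovered in fibroblast m5C RIP (12273) and 92.4% in both tissues (14193). The share was 10.6% in Dnmt1 RIP over input (16558) and 66.7% in m5C RIP over input (14501). The WT comparison of the antibodies gave 68.2% (17124). Of the 4-fold changes, 10.4%, 34.3%, 62.7%, 0%, 4.48% and 17.9% were recovered in the same order. False calls numbered at most 4 in a design. Het and Hom against WT in the Dnmt1 RIP, where the WT libraries are shallower, were not simulated.

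Alternatives were RLE size factors, total counts alone, no filter on low counts, DESeq2 1.42.0, leaving out each library, the replicate number as a block, fits of the 2 genotypes compared, removal of non-polyadenylated RNAs, and Het and Hom together. Added after the data were seen were a GC correction, removal of 4 dominant genes, a block by Fam221b share, genes at least 4 times higher in fibroblast than cortex m5C RIP, and ratios to fibroblast m5C WT library 2 alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.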

Results

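The series compared RNA pulled down with antibodies from mice carrying a dominant mutation in Dnmt1, the maintenance DNA methyltransferase, with RNA from wild type (WT) littermates. An antibody against Dnmt1 was used on formaldehyde-fixed cells of tail fibroblast lines (Dnmt1 RIP), with 2 libraries each from WT, heterozygous (Het) and homozygous (Hom) lines. An antibody against 5-methylcytosine (m5C), a modified RNA base, was used on messenger RNA of fibroblasts (2 WT, 1 Het and 1 Hom library) and of cortex (1 library per genotype). A single library from each tissue was titled input, although its antibody label names IgG, and is called input here. With no input per genotype, a difference between genotypes in RNA pulled down cannot be told from a difference in RNA abundance. The 15 libraries form 11 groups. Counts in genes were 217173 and 463133 for the WT Dnmt1 RIP, 814262 and 804887 for Het, 1029457 and 1362757 for Hom and 228852 for fibroblast input. The fibroblast m5C libraries held 975604 and 1226969 (WT), 2163814 (Het) and 725824 (Hom), and the cortex libraries 1310590 (WT), 1434653 (Het), 2408694 (Hom) and 4913482 (input). Levels are given as CPM, the gene counts of a library scaled to its total, and log2 fold changes are given with their standard error (SE). List averages, levels per kb and shares of a cortex or fibroblast m5C level instead leave 4 dominant genes (Lars2, Gm42418, Gm26917 and Gm10800) out of that total. Without them 376192 of 1029457 counts remain in Hom Dnmt1 RIP library 1 and 95107 of 228852 in fibroblast input. The labels do not say that libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

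Dnmt1 itself (chromosome 9, 20907209 to 20959888, minus strand, mm10, GENCODE M21) was read in every library. In the Dnmt1 RIP it stood at 2430 and 2940 CPM in WT, 1510 and 2020 in Het, and 903 and 8870 in Hom, against 682 in fibroblast input. In fibroblast m5C RIP it was 8800 and 600 CPM in WT, 396 in Het and 694 in Hom. In cortex m5C RIP it was 1630 (WT), 1160 (Het) and 1110 (Hom), with 1130 in cortex input. The mutation changes the protein rather than removing the gene, so these levels do not test the genotype labels. The Y-linked gene Ddx3y was detected in every library except fibroblast input, where it had 0 counts, which allows up to 13.1 CPM; elsewhere it ranged from 10.7 to 85.5 CPM. Xist, the X-inactivation RNA, reached at most 36.8 CPM.

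A few abundant transcripts took unequal shares of the libraries. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462666), held 57.6% of Hom Dnmt1 RIP library 1 (95% exact binomial interval 57.5 to 57.7%), 12.1% of fibroblast m5C WT library 1 and 19.3% of fibroblast input. Gm42418, which overlaps ribosomal RNA sequence on chromosome 17, held 37.5% of fibroblast input (37.3 to 37.7%). Fam221b was at 0.595% of WT library 2, 0.373% of Het library 1 and 0.748% of Hom library 2 of the Dnmt1 RIP, and at no more than 0.009% of the other 3. Together with Gm26917 and Gm10800, Lars2 and Gm42418 made up 58.4% of fibroblast input, which detected 6006 genes, against 17858 to 26250 in the Dnmt1 RIP libraries. The file of fibroblast m5C WT library 1 was at or above that of the Hom library in all 31017 genes and equal to it in 7163 of the 19511 genes detected there.

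Whether RNA recovered in the Dnmt1 RIP differs in Het cells was asked first. Genes of the extracellular matrix, the scaffold that fibroblasts secrete, had the clearest pattern: all 32 measured matrix genes had a higher estimate in Het than in WT, with a median log2 fold change of 1.91. The fibrillar collagen gene Col3a1 (chromosome 1, 45311538 to 45349706) stood at 27.6 and 143 CPM in WT and 1470 and 1120 in Het, a log2 fold change of 3.90 ± 0.84. Loxl1 (chromosome 9, 58287738 to 58313186), which cross-links elastin, went from 18.4 and 17.3 CPM to 329 and 150 (3.91 ± 0.66). Col5a1 (3.28 ± 0.73) and the microfibril gene Fbn1 (2.13 ± 0.48) had estimates of the same sign. Immediate early genes, the first transcribed after a stimulus, had 20 of 22 positive estimates and a median of 1.22 (0.8 to 2.31 over the settings run). Among these were Klf2 (chromosome 8, 72319033 to 72321656; 3.84 ± 0.69), Junb (2.25 ± 0.51; 96.7 and 75.6 CPM in WT, 447 and 281 in Het), Fosb (2.78 ± 0.66) and Ier3 (3.83 ± 1.07).

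In this comparison the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (n = 2 and 2) called 0 of 13589 genes; 868 had an unadjusted p under 0.05, 602 of them higher in Het, and the smallest adjusted p was 0.732. DESeq2 called 31, all higher in Het, of which 8 were matrix genes (Col3a1 3.91, adjusted p = 7.28e-06; Loxl1 3.95, adjusted p = 0.000188), and 23 of the 31 were at least 4 times higher in fibroblast than in cortex m5C RIP. Without Het library 2, which leaves 1 Het library and a spread taken from the WT and Hom pairs alone, edgeR called 38, all higher in Het; these rest on Het library 1 and are no separate evidence. The other genes with the smallest p were the kinase gene Pim1 (5.52 ± 1.03), Col16a1 (2.59 ± 0.50) and the TNF-induced gene Tnfaip2 (2.64 ± 0.50) on the higher side. On the lower side they were the cation channel gene Trpc4 (-2.97 ± 0.70), Fmc1 (-3.30 ± 0.84), the imprinted gene Magel2 (-3.03 ± 0.78), Olfr410 (-4.13 ± 1.07) and Prrg1 (-3.47 ± 0.92). By camera with the preset correlation, the matrix list was higher in Het (adjusted p = 4.75e-28; adjusted p = 0.247 with an estimated correlation), and 22 members passed when adjusted over the list alone. Immediate early genes gave adjusted p = 1.03e-08 (adjusted p = 0.247 with an estimated correlation), with 5 members past the threshold adjusted over the list alone.

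Further lists moved in the same comparison. Collagen genes had 28 of 44 positive estimates and a median of 0.91 (adjusted p = 2.66e-06; adjusted p = 0.398 with an estimated correlation), with 12 past the threshold adjusted over the list alone. Fibroblast markers had 10 of 12 positive and a median of 1.13 (adjusted p = 0.000163; adjusted p = 0.313 with an estimated correlation), 4 of them adjusted over the list alone, among them the receptor gene Pdgfrb (2.27 ± 0.49), Twist1 (5.88 ± 1.55) and Col1a2 (3.67 ± 1.00). The p53 targets, led by Cdkn1a (1.57 ± 0.49) and Sesn2 (2.18 ± 0.69), had a median of 0.66 (adjusted p = 0.0197; adjusted p = 0.328 with an estimated correlation). Interferon response genes had a median of 0.90 (adjusted p = 0.00502; adjusted p = 0.815 with an estimated correlation), but -0.15 without Het library 2, and their test missed the threshold without WT library 2 (median 1.13). Olfactory receptor genes had 56 of 79 negative estimates and a median of -0.93 (adjusted p = 4.66e-07, and 0.221 with an estimated correlation). They lie near the counting floor: all 1092 averaged 5.64 and 6.08 CPM in WT and 4.56 and 4.13 in Het. In the same libraries 3 counts make 13.8, 6.48, 3.68 and 3.73 CPM. This list was not rerun with libraries left out, and a difference in background cannot be told apart from one in RNA bound. Clustered protocadherins, adhesion genes of neurons, had a median of -0.72 (adjusted p = 0.00502; adjusted p = 0.303 with an estimated correlation), losing the call without Het library 2 (-0.58). Synapse and ion channel genes had a median of -0.34 (adjusted p = 0.0119; adjusted p = 0.815 with an estimated correlation), losing it without Het library 2 (-0.15) or WT library 1 (-0.17).

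Lists tied to Dnmt1's known roles did not pass the same test. DNA methylation machinery had a median log2 fold change of -0.06 (adjusted p = 0.943), RNA m5C enzymes and readers -0.25 (adjusted p = 0.434), imprinted genes -0.11 (adjusted p = 0.804) and germline genes, which DNA methylation silences in body cells, -0.48 (adjusted p = 0.434). Markers of another cell type differed between the libraries: macrophage genes averaged 16 and 126 CPM in WT and 20.9 and 430 in Het, with Csf1r, the receptor gene for a macrophage growth factor, at 33.2 in Het library 1 and 328 in Het library 2. Neuron markers averaged 469 and 325 CPM in WT and 304 and 286 in Het.

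**Figure D1:**
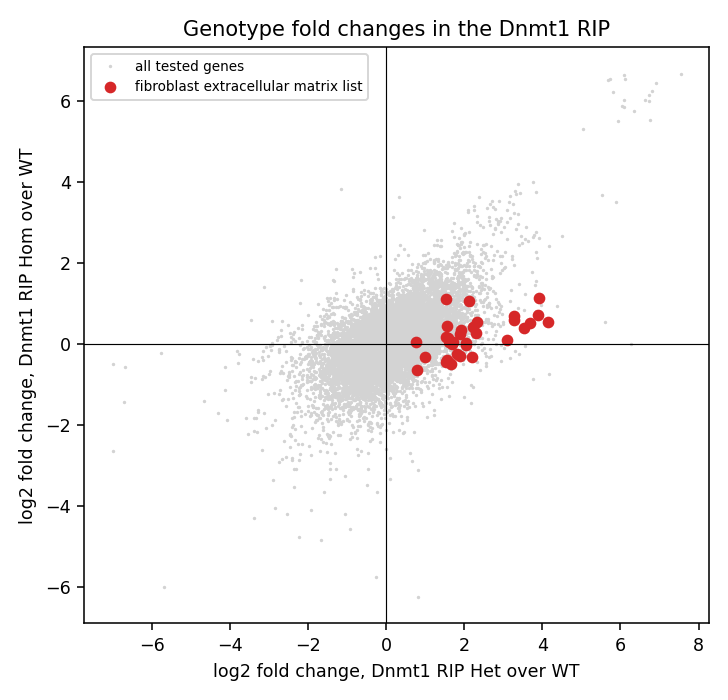
Log2 fold change of Het against WT (horizontal axis) and of Hom against WT (vertical axis) in the Dnmt1 RIP of fibroblasts; grey points are the 13589 tested genes and red points the 32 matrix genes. The red points all lie to the right of 0, with a median of 1.91 for Het, while their median for Hom is 0.15, which turns to -0.07 when libraries are scaled to total counts alone.

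In Hom cells the same question gave no gene list that stood apart. Matrix genes had a median log2 fold change of 0.15 (adjusted p = 0.589), which was -0.07 with total counts as the only scaling, -0.26 without WT library 1, -0.51 without Hom library 2, 1.06 without WT library 2 and 0.51 without Hom library 1. The last pair passed with the preset correlation, and an estimated correlation was not run in these settings. The largest evidence for single genes was for Vhl, whose product marks hypoxia-inducible factors for degradation, at 101 and 49.7 CPM in WT and 5.83 and 16.9 in Hom (-2.27 ± 0.55). It was followed on the lower side by the tRNA-modification gene Elp6 (-2.68 ± 0.66), the phosphatase gene Ppp1ca (-1.64 ± 0.41), Dda1 (-2.04 ± 0.53) and Tubgcp2 (-1.89 ± 0.52). On the higher side were Lmf2, needed for lipase maturation (3.02 ± 0.76; 4.60 and 4.32 CPM against 21.4 and 33.0), Ccdc9 (1.76 ± 0.45), the helicase gene Ddx31 (3.99 ± 1.07), Hps4 (3.52 ± 0.95) and the Notch target Hes1 (2.66 ± 0.74). None passed the edgeR test: 0 of 13589 genes were called, 309 had an unadjusted p under 0.05 (165 higher in Hom), the smallest adjusted p was 1, and DESeq2 also called 0. None of the 36 lists passed the camera test; imprinted genes (-0.01), DNA methylation machinery (0.06) and RNA m5C genes (0.02) had medians near 0. Scaling to total counts alone differs from TMM by -0.54 between Hom and WT, as the difference of mean log2 factors; the matrix median moved by less than this. Dnmt1 RNA had a log2 fold change of 0.92 ± 0.82 in Hom and -0.57 ± 0.82 in Het.

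Hom and Het were also set directly against each other, with the same Het libraries as above, so high counts in these give both results. All 32 matrix genes had a lower estimate in Hom, with a median of -1.96 (-3.14 to -1.49 over the settings run). Examples are Loxl1 (-2.78 ± 0.57), the basement membrane gene Fbln2 (-2.52 ± 0.54), Col3a1 (-3.18 ± 0.80) and Col5a1 (-2.70 ± 0.70). Immediate early genes had a median of -1.32 (-1.52 to -0.67 over the settings run), with Junb (-2.61 ± 0.51), Klf2 (-2.28 ± 0.56), Dusp1 (-1.63 ± 0.42) and Ier2 (-2.51 ± 0.67). Other low estimates were Tnfaip2 (-2.96 ± 0.47), Metrnl (-3.20 ± 0.61), Gas6 (-2.29 ± 0.46) and Pdgfrb (-2.20 ± 0.45), and high ones Prrg1 (4.04 ± 0.86), Gtdc1 (2.15 ± 0.51), the neuronal adaptor gene Dok6 (1.89 ± 0.50), Gnpda2 (2.94 ± 0.84) and Mpv17l (1.90 ± 0.55). edgeR called 0 of 13589 genes (629 at unadjusted p under 0.05, 180 higher in Hom; smallest adjusted p 0.988), DESeq2 called 17, all lower in Hom and 7 of them matrix genes, and edgeR without Het library 2 called 35, with the spread taken from the WT and Hom pairs alone. The matrix list had adjusted p = 4.21e-30 by camera (adjusted p = 0.223 with an estimated correlation), with 25 members past the threshold adjusted over the list alone, and immediate early genes had adjusted p = 9.41e-09 (adjusted p = 0.223 with an estimated correlation), with 6. Fibroblast markers (median -1.44, adjusted p = 3.90e-05; adjusted p = 0.279 with an estimated correlation), macrophage markers (-1.90, adjusted p = 0.0279; adjusted p = 0.765 with an estimated correlation) and ribosomal protein genes (-0.54, adjusted p = 0.00954; adjusted p = 0.845 with an estimated correlation) were also lower in Hom. The macrophage difference rests on Het library 2: as a share of their fibroblast m5C level these markers had medians of 3.23% and 52.3% in Het and 3.19% and 14.3% in Hom, and the complement gene C1qb was at 9.82 and 542 CPM in Het and 3.89 and 109 in Hom. Olfactory receptor genes were higher in Hom (0.56, adjusted p = 0.000831, and 0.223 with an estimated correlation), with the limit of low counts given above.

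Across genes, the Het and Hom fold changes of the Dnmt1 RIP correlated at Pearson's r = 0.597 (Spearman's rho 0.536, 13589 genes, 68.3% of the same sign). Both share the WT libraries, and 20 simulated draws of unchanged groups against them gave a mean r of 0.606 and 69.0% of the same sign. The covariance was 0.437 observed and 0.432 simulated, a difference of 0.00525; the WT pair cannot be split to leave 2 libraries in each part. Genes are not independent replicates, so no p-value is attached. Between the Dnmt1 RIP and the m5C RIP, which share no library, r was 0.116 for Het and 0.00105 for Hom over 11416 genes; the m5C fold changes use a WT library that holds at least the Hom counts, so the value for Hom may be too low.

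Which RNAs the Dnmt1 antibody retains over background was asked against fibroblast input. Some genes with the smallest p are known from neurons, though no list passed as higher in the RIP (camera adjusted p = 0.864 for neuron markers and 0.49 for synapse genes): the synaptic scaffold gene Pclo (364 and 231 CPM), Nrxn3 (336 and 181), Prkcb (313 and 199) and Ppp1r9a (272 and 218) were all read in the WT Dnmt1 RIP and at 0 in input, where 3 counts make 13.1 CPM. Against that floor of 3 counts per library, on the normalised scale, Pclo was at least 9.65-fold higher and Ppp1r9a at least 8.08-fold higher. On the other side were Galnt17 (-3.35 ± 0.53), Mphosph9 (-3.58 ± 0.57), Mief1 (-3.66 ± 0.58), Dtx3l (-4.45 ± 0.77) and Oat (-3.70 ± 0.64). edgeR called 0 of 16558 genes (n = 2 and 1; 4382 at unadjusted p under 0.05, 3528 of them higher in the RIP; smallest adjusted p 0.0576), and DESeq2 called 10 higher and 54 lower. Scaling to total counts alone, whose mean log2 factors differ from TMM by 1.24 between the groups, gave 1192 higher and 19 lower, and edgeR without Het library 1 called 3. The shallow input had 0 counts in most members of many lists, so list medians are not given.

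The m5C RIP of fibroblasts was asked whether RNA recovered by the m5C antibody differs in Het cells, be it by methylation or by abundance. Elastin (Eln, chromosome 5, 134702593 to 134747323), the core protein of elastic fibres, was at 237 and 68.5 CPM in WT and 43.9 in Het (-1.90 ± 0.44, adjusted p = 0.0423). Dnmt1 RNA was at 8800 and 600 CPM in WT and 396 in Het (-3.70 ± 0.74, adjusted p = 0.00218). A pair of uncharacterised genes, named after their values were seen because few genes passed, were also called: the long noncoding gene Gm42047 (chromosome 8, 121833247 to 121841178) was at 22.6 and 37.5 CPM in WT and 158 in Het (2.28 ± 0.38, adjusted p = 9.35e-06), and Gm15564 (chromosome 16, 35966752 to 35983230) at 1540 and 22.8 CPM in WT and 21.3 in Het (-5.32 ± 0.62, adjusted p = 1.58e-13). Gm15564 is annotated as antisense and whether counting used strand is not stated, so its reads may belong to its partner gene. These 4 were the edgeR calls among 12273 genes (n = 2 and 1, 406 at unadjusted p under 0.05); DESeq2 called 0 (23 at unadjusted p under 0.05). The Het arm is 1 library and the spread comes from the WT pair, of which library 1 holds at least the Hom counts, so these calls do not establish an effect of the genotype. The fibroblast m5C Het and Hom tables also have another layout of counts than the WT tables. A difference in counting thus cannot be told apart from genotype here. Against WT library 2 alone, the log2 ratio was -0.61 for Dnmt1, -0.64 for Eln, -0.11 for Gm15564 and 2.01 for Gm42047. With Het and Hom together against WT, 0 genes were called and Eln was at 0.03.

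Brain genes of several cell types were lower in the Het m5C library. All 15 neuron markers had negative estimates (median -0.85, adjusted p = 2.13e-08; adjusted p = 0.865 with an estimated correlation), as did 33 of 34 synapse and ion channel genes (median -0.57, adjusted p = 2.91e-09; adjusted p = 0.865 with an estimated correlation). Astrocyte markers (-0.63, adjusted p = 0.033) and oligodendrocyte markers (-0.50, adjusted p = 0.0254) were lower with them, each with adjusted p = 0.865 with an estimated correlation. As a share of their cortex level, these neuron, astrocyte and oligodendrocyte markers together had medians of 13.3% and 11% in WT and 7.05% in Het. Immediate early genes (-0.52, adjusted p = 3.25e-06) and Hox genes, which set position along the body (-0.68, adjusted p = 0.00141), were lower as lists. Both had adjusted p = 0.865 with an estimated correlation. Over the settings run the median of immediate early genes ranged from -0.52 to -0.13, and their call with the preset correlation was not kept in all. Matrix genes had 30 of 33 positive estimates (median 0.26, adjusted p = 0.000162), including fibronectin, Fn1 (1.14 ± 0.53), and myofibroblast genes 6 of 6 (0.45, adjusted p = 0.00013). These too had adjusted p = 0.865 with an estimated correlation. The matrix median ranged from 0.06 to 0.35 over the settings run, and its call was not kept in all either. Against WT library 2 alone the median was -0.50 for neuron markers, -0.39 for synapse genes, -0.22 for immediate early genes, 0.06 for matrix genes, 0.16 for myofibroblast genes and 0.20 for the 4 Hox genes with enough counts, which for the Hox genes reverses the sign seen against both WT libraries; over all 7445 genes with enough counts it was 0.07.

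In Hom fibroblasts the same m5C comparison called 1 of 12273 genes, Gm15564 (-4.82 ± 0.63, adjusted p = 2.70e-10), and its ratio to WT library 2 alone was 0.28. Dnmt1 (-2.90 ± 0.70, adjusted p = 0.218) and the matrix gene Ltbp2 (62.5 and 404 CPM in WT, 68.9 in Hom; -1.85 ± 0.46) did not pass, nor did Epc2 (-2.12 ± 0.66), Actg2 (-1.81 ± 0.56), the stress-induced gene Atf3 (0.97 ± 0.39), Eln (0.90 ± 0.38), Cbr2 (1.06 ± 0.47), Wfdc17 (0.84 ± 0.38) and Selenop (0.87 ± 0.39). Macrophage markers had 11 of 12 positive estimates (median 0.52, adjusted p = 6.34e-06), among them Csf1r (0.60 ± 0.47), Adgre1 and Cd68, and interferon response genes 24 of 29 (0.37, adjusted p = 0.000234). Hox genes (-0.52, adjusted p = 0.000346), myofibroblast genes (0 of 6 positive; -0.71, adjusted p = 0.000343) and matrix genes (5 of 33 positive; -0.21, adjusted p = 0.00557) were lower as lists. All of these had adjusted p = 0.98 with an estimated correlation, and the matrix median was 0.06 with Het and Hom together. Over the settings run the macrophage median ranged from 0.18 to 0.74. Neither the macrophage nor the matrix list kept its call with the preset correlation in all of them. edgeR found 118 genes at unadjusted p under 0.05, and DESeq2 called 0 (6 at unadjusted p under 0.05). WT library 1 contains at least the counts of the Hom library in every gene, so the estimates against both WT libraries are not independent of Hom. Against WT library 2 alone, without a test, the log2 ratio was 0.10 for Dnmt1, -2.64 for Ltbp2, 2.14 for Atf3, 2.03 for Eln and 2.03 for Selenop. List medians were then 0.74 for macrophage markers, 0.23 for interferon response genes, -1.32 for myofibroblast genes and -0.55 for matrix genes (30 of 33 lower), against -0.16 over all 4970 genes with enough counts. Too few Hox genes had enough counts for a median there.

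**Figure D2:**
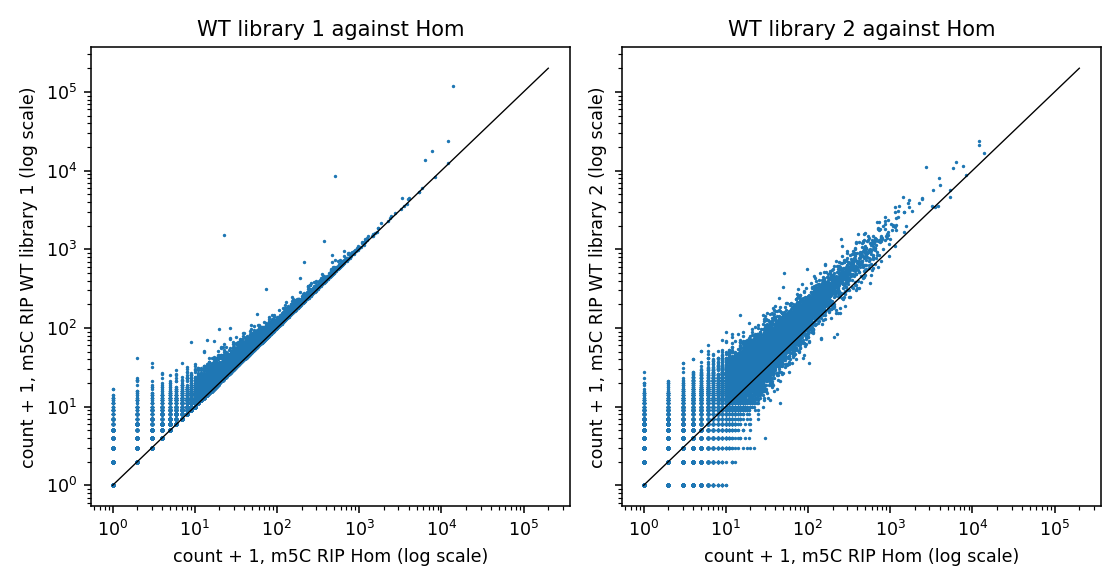
Count plus 1 of each gene in fibroblast m5C WT library 1 and WT library 2 (vertical axes) against the Hom library (horizontal axes), both axes logarithmic, with the line of equal counts; each point is a gene. WT library 1 has 0 of 31017 genes below the line, and 7163 detected genes lie on it.

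To ask what is common to both tissues, the 7 m5C libraries were fitted with tissue as a covariate. In Het, the lowest estimate with the smallest p was Bc1 (chromosome 7, 144914470 to 144914637), a short noncoding RNA of neuronal dendrites (-1.79 ± 0.31, adjusted p = 0.543), at 397 CPM in WT and 119 in Het cortex. In fibroblasts it had 7 and 4 counts in WT and 4 in Het, so this estimate rests on the cortex pair. The immediate early genes Jund (-1.10 ± 0.27) and Ier2 (-1.30 ± 0.32), Scrt1 (-1.03 ± 0.26) and Sema6c (-1.17 ± 0.32) followed, with Efemp1 (1.19 ± 0.26), Fam102b (0.95 ± 0.24), Fem1c (1.19 ± 0.31), Ly6c1 (1.09 ± 0.30) and Gga2 (0.84 ± 0.24) on the higher side. Immediate early genes had 20 of 23 negative estimates (median -0.48, adjusted p = 2.54e-07; 3 adjusted over the list alone), and genes of the mitochondrial genome 11 of 13 positive (0.47, adjusted p = 9.98e-07). Both had adjusted p = 0.901 with an estimated correlation. The first list missed the threshold without the fibroblast Het library (-0.43) and the second without the cortex WT library (0.30). No GC correction was run for this fit. In Hom, Hox genes were lower (median -0.64, adjusted p = 1.73e-05; adjusted p = 0.954 with an estimated correlation), missing the threshold without fibroblast WT library 1 (-0.75). Macrophage markers (0.37, adjusted p = 0.0118; adjusted p = 0.954 with an estimated correlation) fell to a median of 0.00 without the fibroblast Hom library and 0.20 without WT library 2. The muscle gene Neb (-2.03 ± 0.52), Camk2n2 (-1.14 ± 0.35), Ddx11 (-2.04 ± 0.65), Adnp (-1.81 ± 0.61) and the lysosomal protease gene Ctss (0.72 ± 0.24) had the smallest p among those named. edgeR called 0 of 14193 genes in Het (564 at unadjusted p under 0.05; DESeq2 0) and 0 in Hom (122; DESeq2 38, all lower). Leaving out fibroblast WT library 1 gave 10 calls in Het and 17 in Hom, and leaving out WT library 2 gave 1 in each.

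Which RNAs the m5C antibody enriches was tested over the pair of inputs with tissue as a covariate. Cardiac actin, Actc1 (chromosome 2, 114047282 to 114053548), stood at 315 CPM in fibroblast input and 3.08, 0, 4.62 and 1.38 in the fibroblast m5C libraries, and at 3.05 in cortex input and 0 in the cortex m5C libraries (-8.27 ± 0.95, adjusted p = 0.00719). The long noncoding gene Gm43625 (chromosome 5, 146203251 to 146204789) was at 188 and 35.8 CPM in the inputs and at most 2.79 in any m5C library (-7.77, adjusted p = 0.0148). In the Dnmt1 RIP, Actc1 was at 4.6 and 138 CPM in WT, 92.1 and 6.21 in Het and 0 and 164 in Hom. Gm43625 was there at 0 and 4190 in WT, 6590 and 0 in Het and 5.83 and 49.9 in Hom. These genes thus varied strongly within a group, and each tissue has 1 input library, so the calls do not establish depletion by the m5C antibody. Both were named after their values were seen, being the 2 edgeR calls among 14501 genes (582 at unadjusted p under 0.05); without fibroblast m5C WT library 1 or 2 there were 0, without cortex WT 1, without fibroblast input 6 and without cortex input 5621. DESeq2 called 23 higher and 84 lower. Ribosomal protein genes had 81 of 82 positive estimates in m5C RIP over input (median 1.10, adjusted p = 8.14e-11; adjusted p = 0.81 with an estimated correlation) and matrix genes 33 of 33 (1.04, adjusted p = 0.000314; adjusted p = 0.864 with an estimated correlation). Without fibroblast input these medians were -0.02 and -0.44. Nuclear-encoded respiratory chain genes (70 of 75 positive; 0.76, adjusted p = 5.81e-07) were also higher, with adjusted p = 0.81 with an estimated correlation.

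Whether the genotype effect differs between the assays, which differ in antibody and starting material, was tested as an interaction in the 10 fibroblast immunoprecipitation libraries. These are the libraries of the comparisons above, so the interaction is no separate evidence. Its m5C arm is 1 library per mutant against a WT pair whose library 1 holds at least the Hom counts. The Hom interaction is therefore not independent of the Hom library. For Het, all 33 matrix genes had a more positive estimate in the Dnmt1 RIP than in the m5C RIP (median difference 1.74, adjusted p = 1.30e-11; adjusted p = 0.58 with an estimated correlation), as did 22 of 23 immediate early genes (1.69, adjusted p = 6.98e-12; adjusted p = 0.227 with an estimated correlation), 8 of them adjusted over the list alone. Collagen genes gave 1.03 (adjusted p = 0.000452; adjusted p = 0.58 with an estimated correlation). The single genes with the smallest p were Pim1 (6.21 ± 1.23), Klf2 (4.59 ± 1.00), Rab24 (4.65 ± 1.11), Hlx (3.32 ± 0.84) and Hes1 (3.89 ± 0.99). edgeR called 0 of 17124 genes for Het (573 at unadjusted p under 0.05; DESeq2 0; 6 without Dnmt1 RIP Het library 2, which leaves 1 Het library in that assay) and 0 for Hom (203; DESeq2 0), and none of the 36 lists passed for Hom.

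The Dnmt1 RIP and the m5C RIP of WT fibroblasts were also set against each other. The former started from formaldehyde-fixed cells and the latter from messenger RNA, so antibody cannot be told apart from starting material. The WT Dnmt1 RIP libraries also held brain markers at 60.8% and 43.5% of their cortex level, against 13.3% and 11% in WT m5C RIP. Differences below may come from any of these. Genes of connective tissue and immune cells were low in the Dnmt1 RIP and genes of brain cells high. Of 33 matrix genes 32 were lower in the Dnmt1 RIP (median -4.11), for example Loxl1 (-5.60 ± 0.75), Thbs2 (-4.11 ± 0.56), Fbn1 (-3.90 ± 0.58) and the gelatinase gene Mmp2 (-3.34 ± 0.50). Macrophage markers passed the edgeR threshold as lower in 7 of 12 (median -4.04 over the list), including Cx3cr1 (-3.82 ± 0.70), Adgre1 (-4.06 ± 0.86), Cd68 (-4.83 ± 1.04) and Csf1r (-4.01 ± 0.94). Of 34 synapse and ion channel genes 19 passed it as higher (median 1.55 over the list, 26 adjusted over the list alone), such as the glutamate receptor genes Grm5 (1.99 ± 0.41), Grin2a (2.10 ± 0.47) and the calcium channel gene Cacna1b (1.81 ± 0.41). Neuron markers passed it as higher in 5 of 15 (median 1.43 over the list, 13 adjusted over the list alone), with Nefl (1.99 ± 0.45), Rbfox3 (1.89 ± 0.48), Nefm (1.58 ± 0.41) and Syt1 (1.82 ± 0.49). The myelin gene Mobp (2.36 ± 0.50) and the oligodendrocyte factor gene Olig2 (3.01 ± 0.70) rose among 10 oligodendrocyte markers, and Aqp4 (2.08 ± 0.63) and Slc1a3 (1.36 ± 0.42) among 9 astrocyte markers. These signs were the same with the other scalings tried.

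By edgeR, 561 genes were higher and 1784 lower in the Dnmt1 RIP among 17124 (n = 2 and 2; 5286 at unadjusted p under 0.05). The m5C WT library 1 counted here holds at least the Hom counts in every gene, which are 74.4% of its total, so it may not be a second WT library. The split was 882 and 1471 with RLE size factors (a difference of mean log2 factors of 0.20 from TMM), 454 and 406 with total counts alone (0.62) and 426 and 2441 after correction for GC content. DESeq2 gave 508 and 1274. Without Dnmt1 RIP WT library 1 only 3 genes were called, without WT library 2 there were 940, without m5C WT library 1 there were 523 and without m5C WT library 2 there were 0. By camera, adjusted p was 7.13e-28 for matrix genes (adjusted p = 0.126 with an estimated correlation), 1.76e-06 for macrophage markers (adjusted p = 0.293 with an estimated correlation), 1.29e-12 for synapse genes (adjusted p = 0.126 with an estimated correlation) and 9.66e-07 for neuron markers (adjusted p = 0.249 with an estimated correlation). It was 0.00209 for oligodendrocyte markers (adjusted p = 0.126 with an estimated correlation) and 0.00521 for astrocyte markers (adjusted p = 0.255 with an estimated correlation). Ribosomal protein genes passed the edgeR threshold as lower in 30 of 82 (list median -2.11, camera adjusted p = 4.72e-17, and 0.378 with an estimated correlation). Respiratory chain genes did so in 33 of 75 (list median -1.58, camera adjusted p = 1.29e-12, and 0.305 with an estimated correlation).

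Several single genes in this comparison were read in 1 assay alone. Plp2 (0 in both Dnmt1 RIP libraries; 64.6 and 89.7 CPM in m5C RIP) was at least 12-fold lower in the Dnmt1 RIP on the normalised scale, against a floor of 3 counts per library. Likewise Scara5, a ferritin receptor of mesenchymal cells, was at least 6.45-fold lower, the sterol synthesis gene Ebp at least 6.32-fold, the cytokine receptor gene Il2rg at least 5.21-fold and the prostaglandin synthase gene Ptges at least 4.26-fold. The antiviral gene Rsad2, B3gnt3, Dnase1l1, Znrd1, the lipid carrier gene Fabp4, the inflammasome adaptor gene Pycard and Mrps28 were at least 2.75-fold to 3.79-fold lower. In the other direction Klhdc9 (55.3 and 21.6 CPM) was at least 8.65-fold higher in the Dnmt1 RIP, and the olfactory receptor genes Olfr410 and Olfr1262 at least 6.15-fold and 5.54-fold higher. Mrgprx2, Tlx2, Cdcp1, Gpr35, Tekt1, Cd27, Vmn1r211 and Map10 were at least 3.50-fold to 5.42-fold higher. The histamine receptor gene Hrh2 was at 18.4 and 820 CPM in the Dnmt1 RIP and 3.08 and 1.63 in m5C RIP, a log2 fold change of 7.10 ± 1.43 that was 2.12 and not called without Dnmt1 RIP WT library 2.

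**Figure D3:**
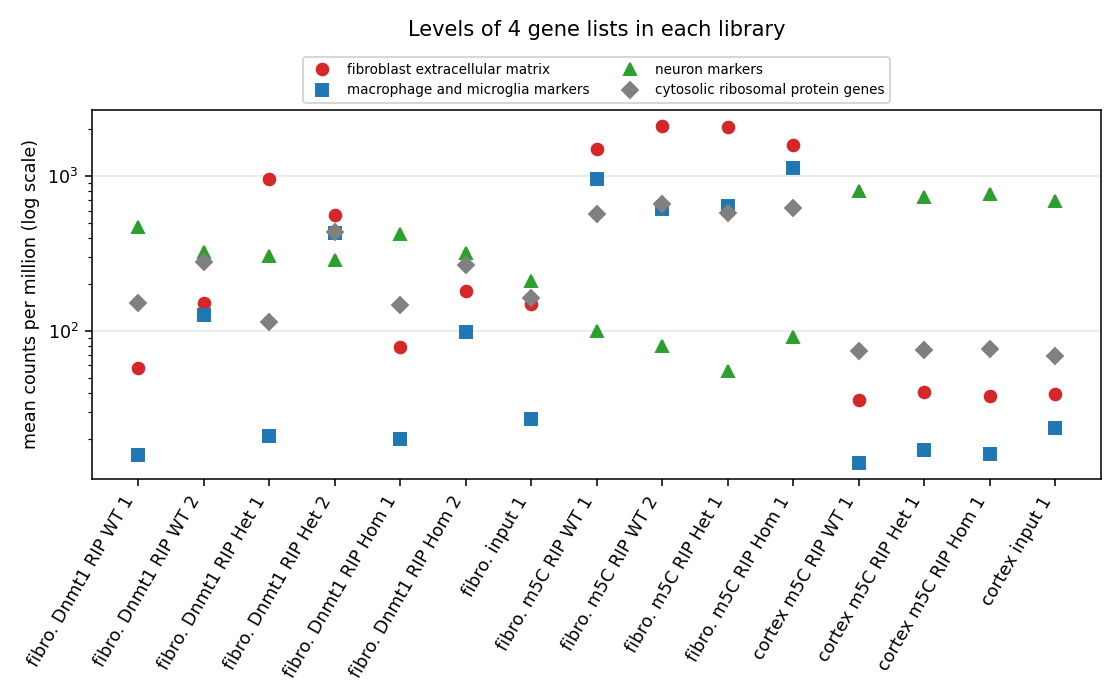
Mean CPM (logarithmic axis), scaled without the 4 dominant genes, of 4 gene lists in each of the 15 libraries, 1 point per list and library. Matrix genes average 58.2 and 152 CPM in WT, 957 and 558 in Het and 78.7 and 180 in Hom Dnmt1 RIP, and neuron markers 286 to 469 there against 55.0 to 101 in fibroblast m5C RIP.

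Brain transcripts in the fibroblast-labelled Dnmt1 RIP were then placed on the scale of cortex. The median level of 33 brain marker genes was 60.8% and 43.5% of that in cortex m5C RIP for the WT Dnmt1 RIP libraries, 41.2% and 39.6% for Het and 57.3% and 45.1% for Hom. It was 17.8% in fibroblast input and 13.3%, 11%, 7.05% and 12.4% in the fibroblast m5C libraries.

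**Figure D4:**
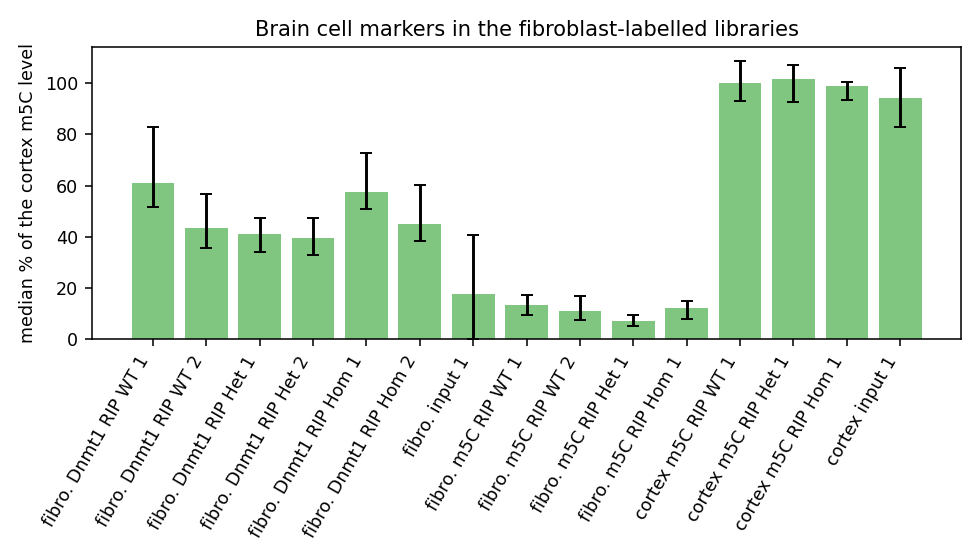
Level of 33 brain marker genes in each fibroblast-labelled library as a percent of their mean cortex m5C RIP level; bars are medians over genes and whiskers the quartiles. The 6 Dnmt1 RIP libraries lie between 39.6% and 60.8%, and the 4 fibroblast m5C libraries between 7.05% and 13.3%.

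Cortex m5C RIP asks whether RNA recovered by the m5C antibody differs in the brain of mutants, be it by methylation or by abundance. With 1 library per genotype there is no replicate check and no test, and both mutants are compared with the same WT library. All 12 measured genes of the mitochondrial genome, which encodes respiratory chain subunits, were higher in Het (median log2 ratio 0.73) and in Hom (0.62), each above 100% of 10000 random lists of the same size and mean expression. Random lists ignore correlation between the members of a list, so percentiles may overstate how unusual a list is. Immediate early genes were lower in Het in 11 of 14 (-0.45, percentile 0) and in Hom in 13 of 15 (-0.40, percentile 0.01), including Jund (-1.52) and Egr4 (-1.54 in Het, -1.42 in Hom). Imprinted genes were at 0.18 in Het (percentile 97.9) and 0.24 in Hom (percentile 99.8), and nuclear long noncoding RNAs at 0.33 in both (percentiles 99.7 and 99.8). Neuron markers were at -0.07 (percentile 35.5) and -0.08 (percentile 7.04). The random lists were not matched on GC content, and no GC correction was run for cortex. Immediate early genes have a median GC content of 54.6%, against 49.7% over the genes tested in the Dnmt1 RIP. A trend with GC content was not tested in cortex and cannot be told apart from these shifts. The WT library that both ratios share stood apart from both mutants: Gm10800 was at 4631 CPM against 410 in Het and 544 in Hom, Gm15564 at 311 against 19.5 and 19.9, and genes silent in both tissues at 0.205 CPM per kb against 0.0551 and 0.0604. Of its entries 86.2% were not aligned, against 79.7% and 79.3%. Ratios alike in both mutants may therefore come from this 1 library.

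In Het cortex 97 genes were at least 2-fold higher and 65 at least 2-fold lower than in WT among 6342 with 50 or more counts in 1 of the libraries, and in Hom 123 and 34 among 7923. The largest Het ratios were Tbc1d4, which acts in insulin-driven glucose uptake (1.68, 56 counts against 15), Ctnnal1 (1.65), Uimc1 (1.62), Foxred1 (1.59) and Hinfp (1.57), and the lowest Bcl7c (-1.99), Rtn4rl2 (-1.76), Bc1 (-1.75, 171 counts against 520) and the adrenergic receptor gene Adra1d (-1.68). In Hom, Fam199x (1.93), Pcdhgb4 (1.89), Unc50 (1.73) and Wdr43 (1.71) were among the largest, and the lowest were Egr4, Adra1d (-1.31), St6galnac4 (-1.29), Zfpm1 (-1.27) and Bcl7c (-1.25).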

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

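The tests of explanations and the tissue interaction were chosen only after results were seen; for GC content the expectation was written before its own result was known.

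Reads outside the main measurement were large in the 6 tables that list them: entries not aligned made up 79.5% for fibroblast m5C Het, 89.5% for fibroblast m5C Hom, 86.2% for cortex WT, 79.7% for cortex Het, 79.3% for cortex Hom and 63.2% for cortex input. The interaction of Het with tissue in m5C RIP gave 3 edgeR calls, in a fit of single libraries whose spread comes from the fibroblast WT pair alone, so they do not establish a difference between the tissues: Gm10722 (-4.39), Gm26870 (-4.25) and Gm21738 (-3.53). They were named after their values were seen. Gm10722 (chromosome 9, 3000922 to 3002330) lies within the span of Gm26870 (3000282 to 3038313), so these calls may not be separate signals. Hom cortex was low as well: Gm10722 was at 128 CPM in WT, 4.18 in Het, 12 in Hom and 27.1 in input, Gm26870 at 105, 8.36, 9.96 and 21.2, and Gm21738 at 394, 36.9, 56 and 275, so these values do not set Het apart from Hom. In the same fit, camera with the preset correlation gave calls for Het in neuron markers (adjusted p = 0.00712), astrocyte markers (0.0433), red blood cell genes (0.000227), synapse and ion channel genes (0.000649) and other non-polyadenylated RNAs (0.0367), and for Hom in genes of the mitochondrial genome (3.36e-05); with an estimated correlation the adjusted p was 0.912 for the former and 0.988 for the last.

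The first pattern weighed is fibroblast m5C WT library 1, which was at or above the Hom library in every gene. Separately sequenced libraries of alike RNA are argued against: 1000 Poisson draws of such a pair put at least 2590 genes below, where 0 were seen, and the next fewest among other pairs of libraries was 163. A file that holds the counts of the Hom library plus others would give that 0, and is the candidate explanation that remains. The remainder is 249780 counts, of which Lars2 takes 41.5% and Dnmt1 3.23%; macrophage markers have 23 counts in it against 9271 in the Hom library. Whether the shared reads belong to WT or Hom cells cannot be read from the counts, and no biological explanation was tested.

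The second pattern is the brain genes in the Dnmt1 RIP of fibroblasts. Genomic DNA or another evenly spread background is argued against, since brain genes per kb were at least 26.7 times as high as genes silent in both tissues. The Dnmt1 mutation is argued against as the source, since the lower WT library stood at 43.5% of the cortex level. RNA or reads of brain in these libraries could account for it: the 33 brain genes kept the cortex order with a Spearman rho of at least 0.943 in each library, and neuron, astrocyte and oligodendrocyte genes lay within 1.31-fold of each other. The fibroblast m5C libraries, with a lower brain share, also kept this order (rho 0.841 to 0.918). The order alone thus does not set the Dnmt1 RIP apart. Whether such RNA entered at the bench or through indexing stays open.

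The third pattern is the matrix genes, higher in Het than in WT Dnmt1 RIP. GC content is argued against as the whole cause, since the median was 1.88 after its removal (1.91 before). A larger share of fibroblast RNA in the Het libraries may contribute and cannot be told apart from binding: other fibroblast-high genes stood at 0.91 times the matrix share in Het library 1 and 1.9 times in Het library 2, but the WT libraries, at 3.57 and 2.83, meet the same bound. As a share of their fibroblast m5C level these other genes stood at 16.3% and 28.2% in WT, 26.3% in Het library 1 (quartiles 11.7 to 58.8%) and 59.9% in Het library 2 (40.5 to 96.4%), and matrix genes at 4.57% and 9.98% in WT and 29% and 31.6% in Het. Het library 1 thus lies between the WT libraries and Het library 2 above both. An effect of the mutation on bound RNA stays open, as does a difference between the cell lines.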

How the results depend on the processing

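The added tests named in the account of the processing were chosen after the results were seen. Counts of called genes moved most. Without the filter on low counts, Dnmt1 RIP gave 192 (Het against WT), 13 (Hom against WT) and 113 (Hom against Het), Dnmt1 RIP over input 1249, fibroblast m5C Het 2, both tissues 10 and 10, m5C over input 100, and the interactions 12 (Het) and 1 (Hom), against 0, 0, 0, 0, 4, 0, 0, 2, 0 and 0. Total counts alone gave 2 for Dnmt1 RIP Hom against WT, 1211 over input, 2 for fibroblast m5C Het, 0 for m5C over input and 860 (717 shared) for the antibodies in WT, against 2345. DESeq2 gave 31, 17, 64, 0 and 0 (fibroblast m5C), 38 (both tissues, Hom) and 107 (m5C over input). Het and Hom together gave 0 in fibroblast m5C RIP, against 4 and 1. Leaving out 1 library gave 0 to 38 for Dnmt1 RIP Het against WT, 0 to 35 for Hom against Het, 0 to 3 over input, 0 to 10 and 0 to 17 for both tissues, 0 to 5621 for m5C over input, 0 to 6 for the Het interaction and 0 to 3158 for the antibodies in WT. Leaving out a WT library in the fibroblast m5C fit leaves no residual degree of freedom and was not run. The labels give replicate numbers no meaning, and correlations of deviations between genotypes were -0.00702, 0.237 and 0.0634. Macrophage markers were lower in library 1 of WT, Het and Hom (medians 2.43%, 3.23% and 3.19% of their fibroblast m5C level) than in library 2 (12.5%, 52.3% and 14.3%). Fam221b, high in Het library 1 and in library 2 of WT and Hom, did not follow the number. An effect of replicate number is thus not ruled out. The replicate block gave 0, 0 and 0 calls in the Dnmt1 RIP. Of 422 list tests in 12 comparisons, 87 passed with the preset and 0 with an estimated correlation. Directions reversed for matrix genes in Dnmt1 RIP Hom (-0.07 with total counts, a median near 0 whose sign carries no weight, and -0.51 to 1.06 leaving out 1 library), interferon genes in Dnmt1 RIP Het (-0.15 to 1.27), ribosomal protein and matrix genes in m5C over input (-0.02 to 3.61 and -0.44 to 4.45), and matrix genes and Eln in fibroblast m5C with Het and Hom together (0.06 and 0.03). Against WT library 2 alone, Gm15564 in fibroblast m5C Hom reversed to 0.28. Hox genes in fibroblast m5C Het stood at 0.20 there over the 4 members with enough counts, against -0.68 over 21 members in the fit, so the members differ as well. The cause was not tested, except that fewer libraries leave less to estimate the spread. Other named genes kept direction and side in 236 settings, were not called in 128 (18 and 2 of them with no adjusted p from DESeq2) and moved toward 0 in 3; lists kept theirs in 300, lost it in 22 and gained a call in 2. The matrix median for Dnmt1 RIP Het stayed between 1.56 and 3.04 in all settings run (adjusted p 8.57e-41 to 4.93e-11 with the preset correlation; adjusted p = 0.247 with an estimated correlation in the planned fit). Genes at least 2-fold apart in cortex numbered 141 to 172 (Het) and 135 to 183 (Hom). Depth limits Dnmt1 RIP WT library 1 and fibroblast input most, where 3 counts make 13.8 and 13.1 CPM.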

Other observations

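The lists below come from the fits already described and were picked out after their results were seen; the tests themselves were planned.

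Other gene groups differed between the Dnmt1 RIP and the m5C RIP in WT fibroblasts. In this paragraph, counts of lower or higher members are of genes past the edgeR threshold, and medians are over the whole list. Of 23 p53 targets, genes switched on by DNA damage, 7 were lower in the Dnmt1 RIP than in m5C RIP (median -1.55, adjusted p = 4.97e-05; adjusted p = 0.126 with an estimated correlation). Cell cycle genes were lower in 8 of 36 (-1.10, adjusted p = 0.000116; adjusted p = 0.285 with an estimated correlation) and interferon response genes in 7 of 30 (-1.57, or -1.56 with its 1 gene at 0 set to the floor; adjusted p = 0.000127; adjusted p = 0.393 with an estimated correlation). Immediate early genes were lower in 15 of 23 and higher in 1 (median -2.25, adjusted p = 1.15e-06; adjusted p = 0.126 with an estimated correlation), and fibroblast markers lower in 8 of 13 (-2.75, adjusted p = 6.96e-06; adjusted p = 0.228 with an estimated correlation). Olfactory receptor genes, silent in most tissues, had 292 positive estimates among 330, of which 4 passed (adjusted p = 2.32e-09 for the list, and 0.126 with an estimated correlation). All 1092 averaged 5.64 and 6.08 CPM in the Dnmt1 RIP and 1.76 and 1.16 in m5C RIP, below the level of 3 counts in each library. The calls in this paragraph share the dependence on single WT libraries given above, with 3 genes left without Dnmt1 RIP WT library 1 and 0 without m5C WT library 2. They also share the differences in starting material and in brain transcripts.

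Fibroblast-labelled m5C libraries also carried macrophage transcripts, at 965 and 609 mean CPM over the 12 markers in WT, 638 in Het and 1127 in Hom, against 14.2 to 23.7 in the cortex libraries. Of the marker counts in WT library 1, only 0.247% lie beyond those of the Hom library. Its 965 CPM is thus no measurement separate from Hom. In cortex Het, collagen genes had a median log2 ratio of -0.46, at percentile 0.82 of random lists, over 7 genes; in Hom the median was -0.03, at percentile 25.3 over 12 genes.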
